A study of Mus musculus with 4 samples.

How the data were processed

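Per the labels, total RNA of Tsk1/+ mouse skin was extracted with a Qiagen kit for fibrous tissue, and 200 ng was amplified and labelled with an Agilent Quick-Amp kit. The skin channel carried Cy3 and the channel of the common cell-line reference, called UMR, carried Cy5, per the labels. The 4 arrays all had the same dye orientation and form 1 group, so an effect of the dye on a gene cannot be told apart from skin over reference. The deposited values are log ratios of the 2 channels, 1 per probe and array, as the authors left them in the series table. Scanner intensities were not used here, and the background correction, the normalization, the log base and the direction of the ratio are not given in the sources used here.

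The log base and direction were taken from the values. On each array, 49.9% to 58.0% of probes fell on 43 to 47 repeated values, many of them in pairs a fixed distance apart. Among the 40 commonest values of each array, 21 pairs of 3120 lay at the distance of log2 (2 times the log of 2, tolerance 0.001), against 2 for the natural log and 3 for log10. At 2 times the log of 1.5 the contrast was smaller (16, 7 and 3 pairs). The counts were highest for log2 at both distances, so the deposited values were treated as log2 ratios. The median of each deposited column was 0. With 21.4% to 29.1% of the values of an array at exact 0, this median lies among the zeros and does not show that arrays were centred. Centring on a median of 0 could not change the results, so that alternative tests nothing. Genes had not been centred: the SD of gene means over genes was 1.16, against a median SD between arrays of 0.20. All signs were turned after the direction test on the cornified epidermis list (10000 random lists). Which step set each array's centre stays unknown.

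The table holds 41174 probes. In the platform annotation of the probes, 32664 probes have 1 gene symbol, 45 have several and 8465 are not named; the last 2 kinds entered no gene test. By Entrez ID, 32524 probes matched a gene of the GRCm38.p6 annotation, which was used for names only. Probes of a gene were averaged (8511 of 19532 genes have more than 1 probe), and genes with a value on at least 3 arrays were tested. Where probes of a named gene differed by over 1 in their means, their lowest and highest means stand beside its value. Exact zeros were kept as values in the tests as fixed in advance; 3878 probes were listed at 0 on all 4 arrays and 12970 on 1 to 3 arrays. Because a 0 can stand for a spot without a usable ratio, genes listed at 0 on an array are given array by array, and the gene tests, the camera test with a preset correlation and the correlations between arrays were repeated without exact zeros, an alternative chosen after seeing the data.

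Skin over reference was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, mean against 0, two-sided), with Benjamini-Hochberg adjustment; a gene passed at an adjusted p below 0.05 and a mean log2 ratio of at least 1 in size. The arrays were also split by the first and by the second title number, 2 against 2, with no minimum size. Gene lists were tested with limma's cameraPR on moderated t-statistics with a preset correlation of 0.01, adjusted over the 30 lists. They were tested again with camera and an estimated correlation, with which none of the lists passed (smallest adjusted p = 0.192). That version also rests on the few residual degrees of freedom of 4 arrays, so lost calls need not come from gene correlation. For cholesterol and fatty acid synthesis the estimated correlation (-0.029) lay below the preset 0.01. Its unadjusted camera p still rose from 4.42e-09 to 0.0823. Reactome sets came from the fgsea 1.28.0 package, and those with 15 to 500 measured genes were tested. Pearson correlations across genes compared arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

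Before the data were examined, the tests, 30 gene lists and the rule for named genes were fixed. The lists cover cornified epidermis, basal keratinocytes, hair, sebaceous gland, fibrillar collagens, microfibrils and elastic fibres, dermal fibroblasts, TGF-beta response, adipocytes, skeletal muscle, macrophages, T cells, B cells, mast cells, dendritic and Langerhans cells, endothelium, melanocytes, Schwann cells, proliferation, interferon response, inflammatory and type 2 cytokines, hepatocytes, pluripotent cells, neurons, red blood cells, immediate early and stress genes, circadian clock, cholesterol and fatty acid synthesis, ribosomal proteins and sex-linked genes. The rule names Fbn1 first, then the 8 highest and 8 lowest genes past the test with the same sign on all 4 arrays. It then takes from each list the 2 genes with the largest ratios in size and, where signs differ, the 1 most opposite. For the first title number it takes the 5 highest and 5 lowest genes past the test or, if none pass, the 3 highest and 3 lowest by moderated t as values, and for Reactome the 5 highest and 5 lowest sets by p. List genes with an outlying array are given as a count unless their range exceeds 2. Genes named beyond the rule, such as Hspa1b and the genes listed at 0 in the closing section, were chosen after their values were seen.

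The scripts were tested on simulated arrays of 19511 genes with 200 changed genes. Skin over reference recovered 71.0%, 79.0% and 90.5% of genes planted at a log2 ratio of 1.5, 2 and 3, with 1 to 3 calls outside them. Among 1000 simulated lists without a shift, 2.3% had a camera p below 0.05. Genes were simulated as independent, whereas the estimated correlation within the real lists reached 0.69, for skeletal muscle. The simulation therefore does not show how often lists of correlated genes pass. Alternatives covered centring, scaling, probe handling, missing values, title numbers as blocks or averaged, the threshold, the variance prior, the sign, leaving out each array, and the exact zeros and repeated values.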

Results

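RNA from the skin of Tsk1/+ mice was hybridised on 4 two-colour arrays, each against RNA of a common cell-line reference that the labels call UMR. Tsk1/+ mice carry a mutation in the gene for fibrillin-1, an extracellular microfibril protein, and are used as a mouse model of scleroderma; the labels name skin and genotype and give no age, sex or skin site. The series as used here holds 1 group of 4 arrays, with titles numbered 1-1, 1-2, 2-1 and 2-2, and no skin of wild-type mice. The values therefore describe Tsk1/+ skin relative to cultured cells, and no effect of the Tsk1 mutation can be read from them. Nothing in the labels says whether the 4 samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. Fbn1, the mutated gene, had no named probe and was not analysed here. The number of arrays limits the precision.

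The labels give skin as Cy3 and the reference as Cy5 but do not say which was the numerator. The likely direction was read from 14 cornified epidermis genes, whose median deposited value was -3.73, -4.73, -4.77 and -5.0 on arrays 1-1, 1-2, 2-1 and 2-2. None of 10000 random gene lists of the same size was as low on any array. Because cornified cells belong to skin and not to ordinary cultured lines, all signs were turned, and positive log2 ratios below mean skin above reference. Each "higher" and "lower" rests on this reading, and the cornified list is for that reason not evidence of its own. Skin carried Cy3 on all 4 arrays, so each may also hold an effect of the dye that repeats on every array. An exact 0 was listed for 29.1%, 25.6%, 21.4% and 28.0% of probes on arrays 1-1, 1-2, 2-1 and 2-2; a gene is called listed at 0 where this applies.

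Of 19532 genes tested, 2150 were higher and 1466 lower in Tsk1/+ skin than in the reference at an adjusted p below 0.05 and a mean log2 ratio of at least 1 in size. The 8 genes farthest above the reference were led by Kprp, a keratinocyte proline-rich protein (8.68 ± 0.93, SD, n = 4 here and for each value that follows with ±), Myot, a Z-disc protein of striated muscle (7.87 ± 0.21), Cidec, a lipid droplet protein of fat cells (7.69 ± 0.46), and Flg2, a filaggrin family member (7.47 ± 1.01). Elovl4, an elongase of very long fatty acids (7.39 ± 0.82), Cox8b, a cytochrome c oxidase subunit of muscle and brown fat (7.29 ± 0.53), Krt23, a type I keratin (7.25 ± 0.75), and Sec14l4 (7.23 ± 0.58) followed. Adjusted p-values of these 8 genes lay between 0.000211 for Myot and 0.00123 for Flg2.

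The genes farthest below the reference were Cxcl1, a neutrophil-attracting chemokine (-5.68 ± 0.24), Rhox5, a homeobox gene of the reproductive cluster (-5.33 ± 0.42), Msln, the mesothelial surface protein mesothelin (-5.08 ± 0.19), and the simple-epithelium keratins Krt18 (-4.84 ± 0.31) and Krt8 (-4.79 ± 0.19; probes at -5.43 and -4.15). Syce1, a protein of the meiotic synaptonemal complex (-4.78 ± 0.40), the chitinase-like Chil3 (-4.73 ± 0.34) and the interferon-inducible Ifi202b (-4.73 ± 0.15) completed the 8 lowest. Adjusted p-values ranged from 0.000239 for Ifi202b to 0.000559 for Syce1. The counts changed by over 1.5 times with a stricter test: against a 2-fold change, limma's treat called 1338 genes higher and 694 lower.

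**Figure D1:**
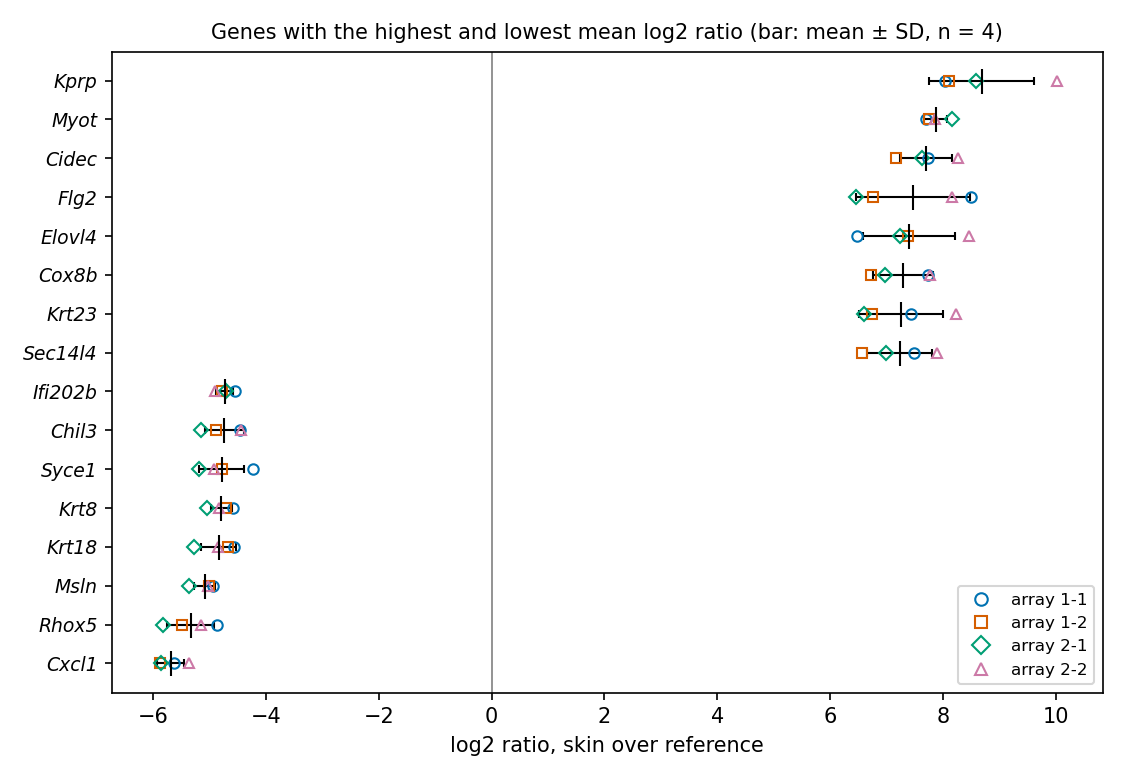
Log2 ratio of skin over reference (x axis) for the 8 genes with the highest and the 8 with the lowest mean ratio. They were taken among genes past the test with the same sign on all 4 arrays, so agreement in sign follows from the selection. Each symbol is 1 array, and the bar marks the mean ± SD over n = 4 arrays. Means run from Kprp at 8.68 to Cxcl1 at -5.68.

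Of the 14 cornified epidermis genes, 10 were higher, among them Lor, the main protein of the cornified envelope (6.81 ± 0.71), and Krtdap (5.97 ± 0.56); this list set the direction. Of 11 basal keratinocyte genes, 9 were higher, led by Perp, a desmosome protein (5.58 ± 0.06), and Col17a1, a hemidesmosome collagen (5.30 ± 0.55; probes at 3.98 and 6.61). That list stood above other genes (limma's camera with a preset correlation, adjusted p = 9.11e-16; adjusted p = 0.192 with an estimated correlation). Of 8 sebaceous gland genes, 4 were higher, with the triglyceride enzyme Dgat2 (4.60 ± 0.43) and the desaturase Scd1 (4.17 ± 0.18) at the top (adjusted p = 0.000420; adjusted p = 0.192 with an estimated correlation). Of 10 cholesterol and fatty acid synthesis genes, 2 were higher: Elovl6, a fatty acid elongase (3.36 ± 0.08), and Fasn, fatty acid synthase (2.54 ± 0.03). Sqle, a cholesterol synthesis enzyme, had the most opposite value (-0.73 ± 0.16) and did not reach the minimum size. The list stood above other genes by camera (adjusted p = 3.31e-08, and 0.192 with an estimated correlation). That call ended when zeros and repeated values were left out (adjusted p = 0.0652). Camera compares moderated t, which was 121 for Fasn and 83.9 for Elovl6, genes with little spread. How far the call rests on these 2 genes was not tested.

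Hair genes differed between arrays. Of 17 hair shaft and root sheath genes, none was higher and 1 was lower, Padi3, a deiminase of the hair follicle (-1.66 ± 0.89, adjusted p = 0.0409); without array 1-2, 2-1 or 2-2 its adjusted p was 0.148, 0.147 and 0.133, and 0.0572 with arrays averaged by first title number. Krt71, an inner root sheath keratin, stood at 6.21 on array 1-1 and at 1.11, 1.58 and 0.69 on arrays 1-2, 2-1 and 2-2 (adjusted p = 0.199). Krt32, a hair keratin, was listed at 0 on array 1-1 and stood at 4.21, 4.55 and 3.48 on the other arrays. It did not pass (adjusted p = 0.0748). It did with the first or second title number as a random block (adjusted p = 0.0394 and 0.0411). It did not with arrays averaged by the first (adjusted p = 0.123). Arrays sharing a number were not the most alike, so a call gained with a block adds no support here. Krt32 also passed without array 1-1 (adjusted p = 0.00856) and without exact zeros (adjusted p = 5.11e-05). The list did not stand apart from other genes (adjusted p = 0.989); its median over genes was 0.61, while the test pointed down.

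**Figure D2:**
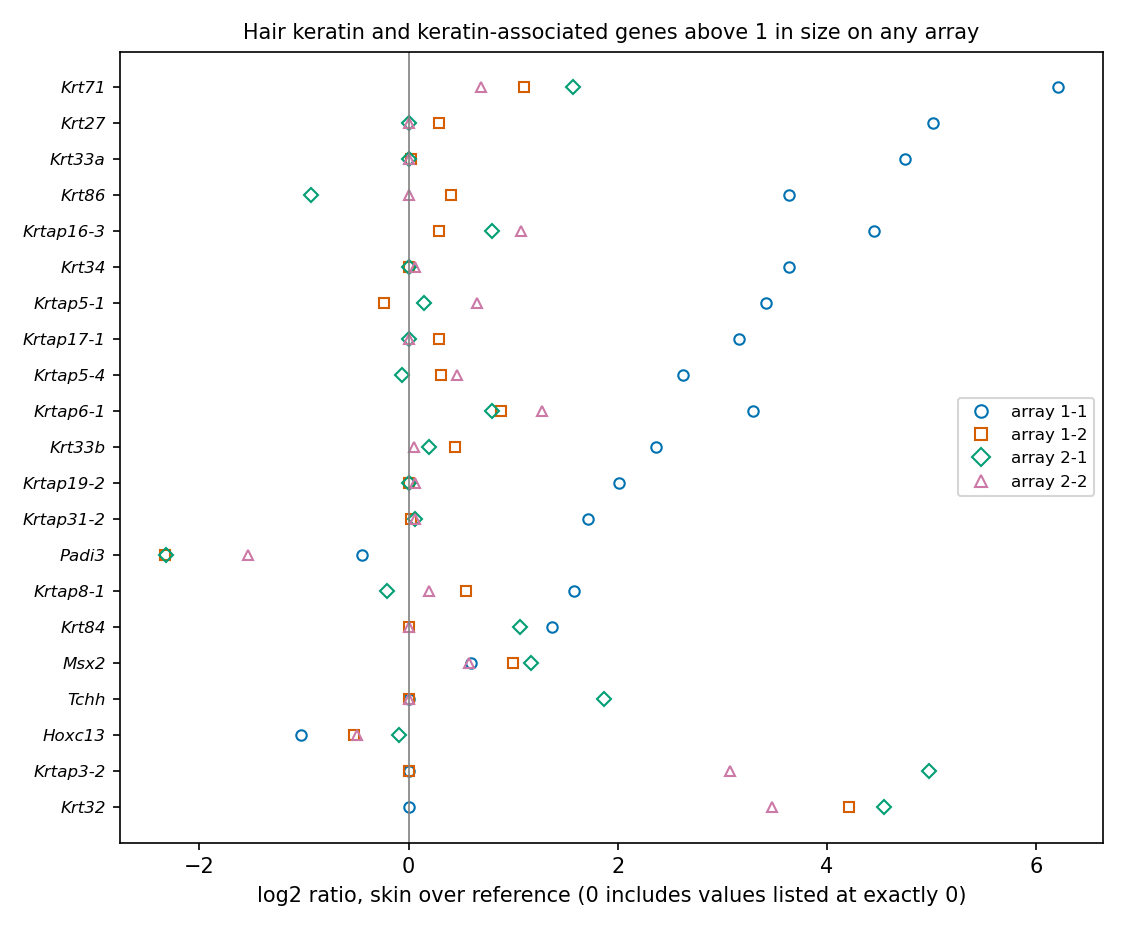
Log2 ratio of skin over reference (x axis) on each of the 4 arrays for the 21 genes of the hair list and of the keratin-associated protein family that exceeded 1 in size on any array, ordered by the excess of array 1-1 over the mean of the other arrays. Array 1-1 stands alone at the right for Krt71 at 6.21, and is listed at 0 for Krt32; values at 0 include spots listed at exactly 0.

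Among extracellular matrix genes, more were higher than lower in skin. Of 8 fibrillar collagen genes, 5 were higher, with Col3a1 at 1.70 ± 0.07 and Col1a1 at 1.67 ± 0.18 (probes from 1.31 to 2.36), while Col11a1, a cartilage collagen, was at -0.01 ± 0.12. The 3 Col3a1 probes ranged from 0.25 to 3.45. The list stood above other genes (adjusted p = 0.00807; adjusted p = 0.192 with an estimated correlation; 0.0528 when exact zeros were left out). Of 16 genes of microfibrils and elastic fibres, 7 were higher and 2 lower. Mfap4 (5.95 ± 0.51) and Mfap5 (5.72 ± 0.48), microfibril-associated proteins, were highest, and Lox, the collagen and elastin cross-linking enzyme, was lowest (-3.08 ± 0.27). This list was above other genes at adjusted p = 0.0288, a call that ended with an estimated correlation (adjusted p = 0.672), without array 1-1 (adjusted p = 0.205), without array 2-2 (adjusted p = 0.0881), with arrays averaged by first title number (adjusted p = 0.253) and when exact zeros were left out (adjusted p = 0.0528). Of 12 dermal fibroblast genes, 5 were higher, led by the matrix proteins Lum (6.40 ± 0.08) and Dpt (4.65 ± 0.51), and 1 was lower, the transcription factor Twist2 (-1.12 ± 0.16); the list's adjusted p was 4.55e-05, and adjusted p = 0.351 with an estimated correlation.

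Genes known to respond to TGF-beta went both ways. Of 15 measured, 4 were higher and 5 lower, with Tgfbi, a matrix protein (5.30 ± 0.20), at the top and Ccn1, a matricellular protein (-2.53 ± 0.08), at the bottom. The list did not stand apart (adjusted p = 0.852); its mean was 0.01, its median -0.49, and the test pointed down.

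Fat and muscle genes formed the lists with the highest medians, 5.11 and 5.50. Without exact zeros their medians were 5.57 and 5.50, and that of cornified epidermis was 5.70. All 10 adipocyte genes measured were higher, with Cidec at 7.69 ± 0.46 and the lipid droplet coat protein Plin1 at 7.17 ± 0.89 (adjusted p = 8.90e-08; adjusted p = 0.192 with an estimated correlation). All 15 skeletal muscle genes were higher, with the myosin heavy chain Myh2 at 6.51 ± 0.76 and the muscle creatine kinase Ckm at 6.48 ± 0.61 (adjusted p = 1.58e-09; adjusted p = 0.301 with an estimated correlation). Their list median was 6.37 on array 2-2 and 5.35, 5.34 and 5.15 on arrays 1-1, 1-2 and 2-1.

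Schwann cell and endothelial lists stood above other genes. All 4 Schwann cell genes measured were higher, including S100b (3.57 ± 0.35) and Mbp, a myelin protein (2.30 ± 0.43), whose 3 probes ranged from 1.15 to 4.54 (adjusted p = 0.00112; adjusted p = 0.192 with an estimated correlation). With arrays of the same first title number averaged, the Schwann cell list and Mbp lost their calls (adjusted p = 0.261 and 0.0518). Of 10 endothelial genes, 6 were higher, such as Tek, the angiopoietin receptor (2.78 ± 0.26; probes at 1.37 and 4.18). Cldn5, an endothelial tight junction protein, stood at 4.75, 6.09 and 6.77 on arrays 1-1, 1-2 and 2-1 and was listed at 0 on array 2-2. It did not pass (adjusted p = 0.0774). It did with the first or second title number as a random block (adjusted p = 0.0364 and 0.0451), with the limit given for Krt32. It did not with arrays averaged by the first (adjusted p = 0.0852). Cldn5 also passed without array 2-2 (adjusted p = 0.0136) and without exact zeros (adjusted p = 9.44e-05). The endothelial list stood above other genes (adjusted p = 0.000122; adjusted p = 0.192 with an estimated correlation). Of 7 melanocyte genes, 2 were higher, among them Pmel, a melanosome matrix protein (2.40 ± 0.69). Dct, a melanin synthesis enzyme, was listed at 0 on array 1-1 and stood at 2.81, 3.53 and 2.15 on the others. Its first probe stood at 5.62 and 7.07 on arrays 1-2 and 2-1, its second at 4.31 on array 2-2, and both were listed at 0 elsewhere. Dct did not pass in the main test or with arrays averaged by the first title number (adjusted p = 0.137). It passed with either title number as a random block (adjusted p = 0.0456 and 0.0423), with the limit given for Krt32. Dct also passed without array 1-1 (adjusted p = 0.0216) and without exact zeros (adjusted p = 0.000314). That list did not stand apart (adjusted p = 0.406).

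Of 11 macrophage genes, 9 were higher, with the complement components C1qb (6.04 ± 0.68) and C1qa (5.14 ± 0.52) at the top, and 1 was lower, the lipopolysaccharide co-receptor Cd14 (-1.12 ± 0.13); the list's adjusted p was 0.000420, and adjusted p = 0.192 with an estimated correlation. Of 8 genes of dendritic and Langerhans cells, 6 were higher, including the MHC class II genes H2-Aa (5.83 ± 0.66) and H2-Eb1 (5.11 ± 0.51). This list's adjusted p of 0.0130 became 0.192 as an adjusted p with an estimated correlation, 0.0762 without array 2-1 and 0.0579 without array 2-2. Of 8 mast cell genes, 4 were higher, with the proteases Cpa3 (5.13 ± 0.52) and Cma1 (4.24 ± 0.74; probes at 2.67 and 5.82), while Tpsab1 was at -1.85 and 0.40 on arrays 1-1 and 1-2 and listed at 0 on the other arrays. The mast cell list did not pass (adjusted p = 0.0806); it did without array 1-2 (adjusted p = 0.0419), with arrays averaged by first title number (adjusted p = 0.000427) and when exact zeros were left out (adjusted p = 0.00452).

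Of 9 T cell genes, 2 were higher, Cd3d (2.31 ± 0.97) and Cd2 (2.28 ± 0.34), and 2 lower, among them Cd5 (-1.46 ± 0.36). Cd3d lost its call without array 1-2, 2-1 or 2-2 (adjusted p = 0.0721, 0.0810 and 0.0905). Of 7 B cell genes, Ighm, the IgM heavy chain, was higher (3.55 ± 0.25, with 4 probes between -0.32 and 5.52), and the receptor component Cd79b (-3.80 ± 0.21) and Ms4a1, which encodes CD20 (-3.77 ± 0.52), were lower. Neither list stood apart (adjusted p = 0.749 for T cells, whose median of 0.02 lay above 0 while the test pointed down, and 0.505 for B cells). Of 20 genes of inflammation and type 2 responses, 4 were higher and 6 lower, with Retnla, a resistin-like protein of alternatively activated macrophages (5.88 ± 0.81), and Chil3 (-4.73 ± 0.34) at the ends. The list as a whole lay below other genes at adjusted p = 0.0312, with a median of -0.12 and a mean of 0.16; the call ended with an estimated correlation (adjusted p = 0.422), without array 2-2 (adjusted p = 0.641), with arrays averaged by first title number (adjusted p = 0.401) and when exact zeros were left out (adjusted p = 0.181). Of 12 interferon response genes, Ifit3 was higher (1.53 ± 0.34) and Usp18 lower (-1.24 ± 0.16), and the list did not stand apart (adjusted p = 0.560).

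All 21 measured genes of the proliferation list were lower, with Aurkb, a mitotic kinase, at -3.06 ± 0.37 and Mki67 at -2.83 ± 0.14. Their median was -2.25, and the list stood below other genes (adjusted p = 1.49e-33; adjusted p = 0.192 with an estimated correlation). Of 13 ribosomal protein genes, 3 were lower, including Rpl3 (-1.16 ± 0.14) and Rps6 (-1.10 ± 0.24), while Rpl13a was at 0.08 ± 0.05. Without zeros and repeated values Rps6 was at -0.89, under the minimum size. The ribosomal list's adjusted p was 0.0178, and 0.0579 without array 2-2. With an estimated correlation its adjusted p was 0.192.

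Of 11 immediate early and stress genes, 2 were higher, the heat shock genes Hspa1a (3.89 ± 0.20) and its near-identical copy Hspa1b, which probes may not tell apart, and 6 were lower, such as the transcription factor Egr1 (-3.16 ± 0.41). The list lay below other genes at adjusted p = 0.0355, a call that ended with an estimated correlation (adjusted p = 0.223), without array 1-1 (adjusted p = 0.144), without array 2-2 (adjusted p = 0.877) and when exact zeros were left out (adjusted p = 0.181). Of 14 circadian clock genes, 2 were higher, including the clock output factor Hlf (2.30 ± 0.32), and 1 was lower, the clock repressor Ciart (-1.37 ± 0.42), which lost its call without array 1-2 (adjusted p = 0.0537); the list did not stand apart (adjusted p = 0.499).

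The remaining lists did not stand apart from other genes with all 4 arrays as replicates. Of 10 hepatocyte genes, Afp, alpha-fetoprotein, was lower (-3.94 ± 0.40) and none was higher; Ahsg was at -0.44 ± 0.62, and Alb, albumin, stood at 1.41 on array 1-2 and was listed at 0 on the others (list adjusted p = 0.554). None of 8 neuron genes passed, with Stmn2 at -0.98 ± 0.09 (probes at -1.90 and -0.06), Elavl4 at -0.34 ± 0.38 and Syp at 1.11 on array 1-2 and listed at 0 on the others (list adjusted p = 0.505, with a median of 0.04, a mean of -0.10 and a test that pointed down). Stmn2 did pass without array 2-2 (-1.02, adjusted p = 0.00417) and without exact zeros (-1.19, adjusted p = 0.000626). None of 10 pluripotency genes passed: Utf1 was at 0.97 and 0.69 on arrays 1-1 and 2-2 and listed at 0 on the other arrays, Dppa5a was at 0.27 ± 0.13, and Lin28a at -0.40 on array 2-1 and listed at 0 on the others (list adjusted p = 0.989; the median was 0.01 while the test pointed down). Of 4 red blood cell genes, the haemoglobin gene Hba-a1 was higher (3.71 ± 0.32), while Alas2 stood at 0.61 and 1.58 on arrays 1-2 and 2-1 and was listed at 0 on the other arrays (list adjusted p = 0.465; 0.0118 with arrays averaged by first title number). Of 4 sex-linked genes, Xist, the X-inactivation RNA, was higher (1.01 ± 0.34; probes from 0.35 to 2.02), and the Y-linked genes Eif2s3y (-3.59 ± 0.75) and Kdm5d (-2.43 ± 0.45) were lower, each with the same sign on all 4 arrays (list adjusted p = 0.505). The Xist call ended under quantile normalization, where its mean was 0.9989, with the median of its 4 probes (0.88), without array 1-2 (0.89), and without array 2-1 or 2-2 (adjusted p = 0.0637 and 0.0554). Adjusted over the list alone, the counts were those given above for all but 6 lists: cornified epidermis had 11 higher, sebaceous gland 6, macrophages 10, endothelium 7 and inflammation 5, and the hair list had 0 lower.

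**Figure D3:**
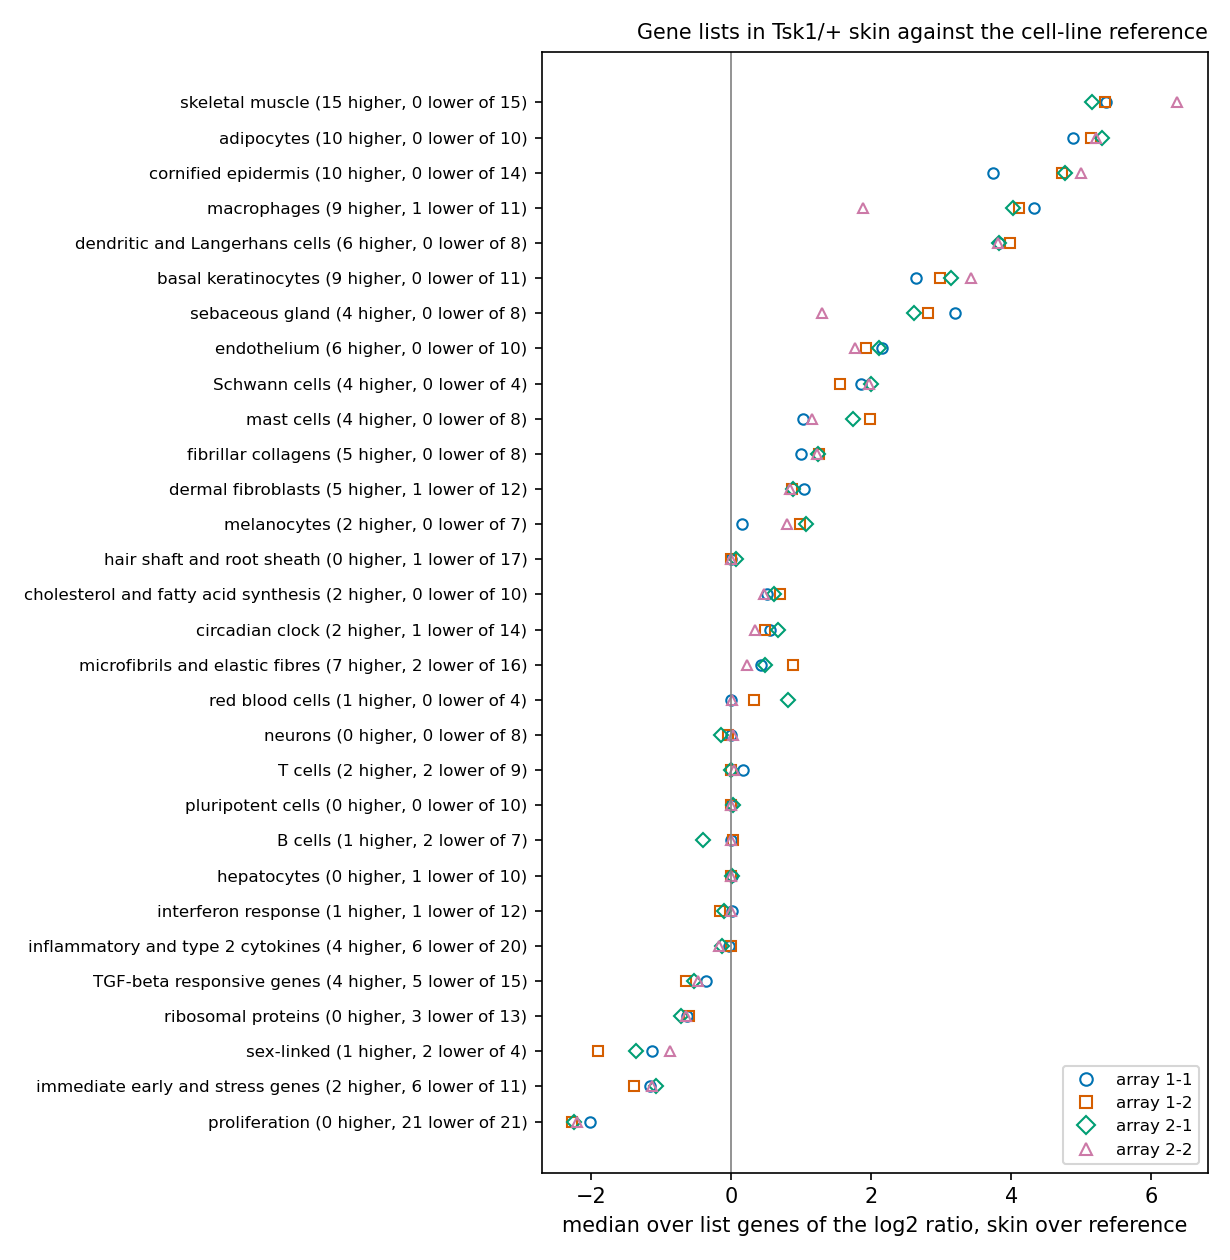
Median log2 ratio of skin over reference (x axis) over the measured genes of each of the 30 lists fixed before the data were examined, with 1 symbol for each of the 4 arrays; the labels give how many genes were higher or lower at an adjusted p below 0.05 and at least 1 in size. Skeletal muscle lies farthest to the right, with array 2-2 at 6.37, and proliferation farthest to the left, with 21 of 21 genes lower.

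Across 710 Reactome pathways, 58 were higher and 168 lower (limma's camera with a preset correlation, adjusted p below 0.05). The higher count was 35 without array 2-2 and 33 with arrays of the same first title number averaged. The highest by p were triglyceride biosynthesis, with 15 of 36 genes higher and 2 lower (adjusted p = 2.17e-06), and the metabolism of fatty acids, triacylglycerol and ketone bodies, with 30 of 80 higher (adjusted p = 6.02e-06). Fatty acyl-CoA biosynthesis (8 of 20 higher, adjusted p = 1.66e-05), striated muscle contraction (19 of 31, adjusted p = 6.02e-05) and muscle contraction (27 of 58, adjusted p = 0.000128) followed. The lowest were activation of the pre-replicative complex, with 17 of 29 genes lower (adjusted p = 2.43e-25), DNA strand elongation (23 of 32, adjusted p = 2.73e-23) and activation of ATR under replication stress (21 of 37, adjusted p = 1.15e-20). G2/M checkpoints (25 of 50) and mitotic prometaphase (53 of 94) both had an adjusted p of 8.62e-18. With an estimated correlation, the unadjusted p of limma's camera was 0.0727 for fatty acyl-CoA biosynthesis, 0.244 for striated muscle contraction and 0.157 for muscle contraction, and between 0.00510 and 0.0419 for the other 7. Only the sets named here were refitted, without adjustment over the 710, so how many of the 58 and 168 calls would hold is not known.

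The titles carry 2 numbers of unstated meaning, and both were compared to see whether arrays that share a number were alike. Between first number 2 and first number 1, limma called no gene (782 genes at an unadjusted p below 0.05, smallest adjusted p = 0.243), and no gene list passed (smallest adjusted p = 0.333, for hepatocytes). By moderated t, the most extreme genes were Cldn10, Unc5a and Bpifc, at 3.64, 4.41 and 3.73 on array 2-1 and 3.76, 4.2 and 3.53 on array 2-2 and listed at 0 on arrays 1-1 and 1-2, and Asb14, Cd5l and Gfra3, at 5.17, 2.67 and 4.01 on array 1-1 and 4.97, 2.75 and 3.72 on array 1-2 and listed at 0 on arrays 2-1 and 2-2. Between second number 2 and second number 1, limma called 1 gene, Scin, an actin-severing protein, at 7.0 and 7.05 on arrays 1-2 and 2-2 and listed at 0 on arrays 1-1 and 2-1 (adjusted p = 0.0296; 968 genes at an unadjusted p below 0.05). Without exact zeros, limma called no gene for either number, with 358 and 402 genes at an unadjusted p below 0.05. For both numbers these counts lay below the share of 0.05 that chance gives, out of 19532 genes tested, or 13642 without exact zeros. Tested on simulated arrays, 2 against 2 recovered none of 200 genes planted at a log2 difference of 2 and 39.0% of 200 planted at 3.

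The arrays most alike shared neither number. Over 19511 genes, which are not independent replicates, Pearson's r across genes was 0.918 between arrays 1-2 and 2-1. It was 0.888 and 0.870 for the pairs with the same first number, 0.867 and 0.892 for those with the same second number, and 0.885 between arrays 1-1 and 2-2.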

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

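In 120 groups of 4 values (list medians, named genes and array shares), arrays far from the others were looked for with Dixon's test at 95%. Chance passes it in about 1 of 20 groups of continuous normal values, a rate that does not hold where exact zeros tie. Where all other arrays lie at exact 0, any other value passes, as for the hair and pluripotency medians on array 2-1. Among the named genes, 9 had an outlying array, 1 of them with a range above 2. Of the tests of explanations below, those on spots left out without regard to their ratio and on a random fault of array 1-1 were chosen after the results were seen.

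Among list medians, fibrillar collagens were lowest on array 1-1 (1.00, others 1.23 to 1.26), and dendritic and Langerhans cells highest on array 1-2 (3.98, others 3.81 to 3.83); without exact zeros array 1-2 was no longer highest (4.67, against 5.17, 4.15 and 5.24 on arrays 1-1, 2-1 and 2-2). Skeletal muscle was highest on array 2-2 (6.37, others 5.15 to 5.35). The medians of B cells (-0.40), hair genes (0.066) and pluripotency genes (0.0165) stood apart on array 2-1, where the other arrays lay at or near 0. Without exact zeros the B cell median stayed lowest on array 2-1 (-0.67, others 0.155 to 0.385). The hair median was then highest on array 1-1, against 0.40, 0.44 and 0.32 on arrays 1-2, 2-1 and 2-2. The pluripotency median, over 2 to 6 genes, was then lowest on array 2-1 (0.066, others 0.187 to 0.712). Of 320 list genes, 48 had an outlying array, 10 of them with a range above 2.

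The macrophage median was 1.89 on array 2-2 and between 4.03 and 4.32 on the others, and Mrc1, the mannose receptor, was listed at 0 on array 2-2 and stood at 6.63, 6.09 and 6.66 on arrays 1-1, 1-2 and 2-1. Without exact zeros that array's macrophage median was 3.52. Exact zeros of this kind recur: of 597 probes that exceeded 2 in size on their other arrays and had a zero on 1 to 3 arrays, 98.5% lay above the reference, against 71.3% of 1853 probes of that size without a zero, which argues against spots left out without regard to their ratio. For 114 genes that had another probe, loss of expression on the array with the zero is argued against in most of 329 pooled comparisons. Their other probes changed there by a median of -0.36 (95% bootstrap interval -0.57 to -0.21). Of these values, 24.9% were listed at 0 as well. Genes with several probes, such as Ttn, entered many times. A median can hide such a part, so loss of expression in some of these genes is not excluded. The median was pooled over genes and arrays, so loss of Mrc1 or of macrophage genes on array 2-2 was not tested by itself. A reference signal at or below background, written as 0, may account for zeros and stays open: zeros made up 7.46% of values where the other arrays averaged above 5 and 6.70% where they averaged 1 to 3, with arrays going opposite ways (17.0% against 8.16% on array 2-2, 9.54% and slightly fewer than in the lower range on array 1-1, 1.96% against 5.38% on array 1-2, 1.93% against 3.13% on array 2-1), and none of 764 values below -3; no biological explanation other than loss of expression was tested.

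The gene Krt71 stood at 6.21 on array 1-1 and between 0.69 and 1.58 on the others, and Krt27, Krt33a, Krt34 and Krt33b were outlying on the same array, at 5.01, 4.75, 3.64 and 2.36 against at most 0.44 elsewhere. A random fault of array 1-1 is argued against, since with the hair list left out, 5 of the 16 genes that exceeded each other array by over 2 there were keratin-associated genes (0.0344 expected); the test was narrowed to these genes with their values already seen. Signal shared between near-identical keratin probes could not be excluded for the hair keratins: keratin-associated protein genes, another family, had a median excess of 0.24 on array 1-1 (95% bootstrap interval 0.02 to 0.79), although Krtap16-3, Krtap5-1, Krtap17-1, Krtap5-4 and Krtap6-1 exceeded each other array by over 2. The hair list itself was not uniform, as Krt32 was listed at 0 on array 1-1. No biological explanation is given by the design, which has 1 group.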

How the results depend on the processing

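The alternatives without exact zeros or repeated values were chosen after seeing the data. Centring could not change any count, as the median of each array was already 0. Of 3616 genes past the test, the count lay between 3317 and 3636 with 1 array left out. It stayed within 1.5 times under quantile scaling, probe medians, missing-value limits, averaging or blocking by title number and the variance prior. The same held without zeros (4274) or zeros and repeated values (4371). The count was 2032 with treat against 2-fold, 8404 with no minimum size and 6102 when each of 32664 probes was tested, as those settings change the threshold or the features counted. With the sign turned the 3616 calls exchange higher and lower. Of 30 lists, 17 passed with the preset correlation and 0 with an estimated one, and leaving out arrays gave 12 to 18 with the preset one. The version with an estimated correlation rests on the few residual degrees of freedom of 4 arrays. Its 0 calls therefore do not show that gene correlation accounts for the 17. By fry, which tests each list by itself, 25 moved on balance (18 higher, 7 lower), 8 of them without a camera call: mast cells, melanocytes, hepatocytes, neurons, red blood cells, circadian clock, sex-linked and, with its direction turned, pluripotency (adjusted p = 0.00146). Reactome gave 226 sets, 169 with arrays averaged by first number (33 higher) and 187 to 215 with an array left out (35 higher without array 2-2). For the second title number the 1 call became 0 under quantile scaling, with the first number as covariate, without zeros, and with any array left out; the first number gave 0 genes throughout, and its lists 0 to 4 with an array left out, where an arm has 1 array that is assumed to vary like the other arm. The correlation of arrays 1-2 and 2-1 was 0.83 by Spearman, 0.961 without zeros and 0.984 without zeros and repeated values, the highest of the 6 pairs each time. The direction list had a median of -4.56 over arrays, -3.73 on array 1-1 alone, -3.05 with basal keratinocyte genes and -0.0165 with hair genes. Of 88 named genes, 69 kept direction and call under each alternative that was fitted to them (82 could be fitted without zeros, 77 without zeros and repeated values; probes taken singly were not compared gene by gene), and 67 of these also with no minimum size, where Sqle, Stmn2 and Dppa5a gained calls; Col11a1 changed sign under quantile scaling (0.0026), without zeros (0.051) and without array 1-2, 2-1 or 2-2 (0.025, 0.0081 and 0.0086; -0.063 without array 1-1), and Tpsab1 without array 1-1 (0.13; -0.615 without array 1-2), neither past the test. Except where named, the cause was not tested. Signal over background is unknown here. Title numbers as random blocks gave 3820 and 3790 genes. The deviations from the gene means correlated at -0.390 and -0.462 for pairs sharing the first number. For pairs sharing the second they correlated at -0.460 and -0.380. All lay below the -0.333 expected with no structure. A block whose arrays are less alike than others can shrink the error of the mean, so calls gained with blocks add no support. No pairing of skin samples between groups was possible because there is no second group to pair with.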

Other observations

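Of the tests below, the split of arrays that neither title number makes and the comparison without zeros and repeated values were chosen after the results were seen.

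Leaving out exact zeros added 658 genes to those past the test of skin over reference, 486 of them higher in skin, and removed none of the 3616. Mrc1, Cldn5 and Dct were among the 658. Where the other values of a gene agree in sign, leaving out a 0 moves its mean away from 0, so gains are largely built in. Genes tested also fell from 19532 to 15102, which eases the adjustment, and limma's variance prior was fitted anew to these genes. Limma's adjusted p fell even for genes without a 0, whose values were unchanged: Kprp from 0.000773 to 4.38e-06 and Cd3d from 0.0210 to 0.00140. Cldn5, with the same values in both fits, had 0.0136 without array 2-2 and 9.44e-05 without exact zeros. A gain therefore need not come from the zeros of the gene itself. The share of each part was not tested. The desmosomal cadherin Dsg1a was listed at 0 on array 1-1 and stood at 7.92, 7.70 and 6.85 on arrays 1-2, 2-1 and 2-2. Likewise Ccl11, the eosinophil chemokine eotaxin, stood at 5.54, 5.52 and 4.74 on arrays 1-1, 1-2 and 2-1 and was listed at 0 on array 2-2. Awat2, a wax synthase of the sebaceous gland, stood at 4.58, 4.25 and 3.81 on the same arrays and was listed at 0 on array 2-2.

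A hypothesis for the hair keratins of array 1-1 is that its skin held follicles in the growth phase. Genes of growing follicles that are not keratins were tested: over 10 such genes the median of array 1-1 minus the mean of the others was -0.30 (95% bootstrap interval -0.95 to 0.53), which does not decide. S100a3, a hair cuticle protein, stood at 1.70 on array 1-1 and at -0.04, -0.47 and 0.32 on arrays 1-2, 2-1 and 2-2, while Dlx3, Foxn1 and Crym were listed at 0 on array 1-1. Foxn1 was also listed at 0 on array 1-2, and Crym on arrays 1-2 and 2-1, so of these 3 only Dlx3 sets array 1-1 apart (1.11, 1.58 and 0.996 on the others). The hypothesis stays open, and so does sharing of probe signal.

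Arrays 1-2 and 2-1 were most alike although they share neither number. The deviations of the 2 arrays from the gene means correlated at -0.073 over all genes and at 0.204 without zeros and repeated values, against -0.172 for the next pair and -0.333 expected of a pair among 4 arrays with no structure, so zeros and repeated values do not account for the whole of it. With each array's smooth trend on the mean ratio removed, the correlation was 0.142 against -0.236, which argues against different compression of the ratios as the whole cause. Between these arrays and the other 2, a split taken because these 2 were most alike, limma called no gene (smallest adjusted p = 0.0658), with 2135 genes at an unadjusted p below 0.05. What the arrays share is not given in the labels; no biological explanation was tested.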
